A study of Mus musculus with 60 samples.

How the data were processed

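RNA of skin, kidney, lung, liver, spleen and skeletal muscle was sequenced by the authors from TruSeq Stranded Total RNA libraries of column-extracted (RNeasy) total RNA, 1 library per mouse tissue sample and 60 in all. The deposited values are raw counts per Ensembl gene, unnormalised, for 52636 genes, and each library's own deposited table held the same values as its column in the table of the whole series. Per the labels the genome build was GRCm38; the aligner, the counting tool, the annotation release and the strand setting are not given in the sources used here. Gene identifiers were matched to symbols and positions in the GENCODE vM21 annotation, which gave a symbol to 52403 of them and none to 233, and the unmatched genes held at most 0.0614% of a library's counts.

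Groups followed the labels for tissue, genotype and treatment: 3 libraries per arm in 4F mice and 2 per arm in B6 mice. The labels give untreated B6 mice an age of 25 months where the series text gives 26 months. They describe the B6 treatment in the words used for inducing the cassette, although the strain given has no cassette, and the treatment protocol names 10 months for all mice where the series text gives 5 months for B6. Replicate numbers were given in the order of the deposited samples, and no label pairs libraries across arms. Library totals were lowest at 18517963 and highest at 43176392 counts. A count of 0 allows a true level of up to 3 counts of the library's total, and this limit covers counting error only. For a gene with no count in an arm, a bound on its fold change set that arm at 3 counts over its libraries together, and medians of lists with such members were computed again with these at their bounds.

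Each tissue was fitted alone with edgeR 4.0.16 in R 4.3.3, with all 10 libraries, the 4 arms and sex in the model and 5 residual degrees of freedom. Genes were kept by filterByExpr at its defaults (count minimum 10, total minimum 15), scaled by TMM, fitted by quasi-likelihood with robust dispersions and tested for 3 contrasts: doxycycline against none in 4F mice, the same in B6 mice, and the difference of these effects. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in the tissue. All log2 fold changes carry the standard error from that fit; levels are CPM, counts scaled to library size, with the SD over libraries. DESeq2 1.42.0 was run on the same design as an alternative.

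Of 66 gene lists fixed in advance, those for the tissue with at least 4 tested members were tested by camera (limma 3.58.1) on the edgeR fit, with its preset correlation of 0.01 and again with a correlation estimated per list, and by fry, which asks whether the members move one way and does not compare them with other genes. Adjusted p-values of lists are over the lists tested in the tissue. Members of a list were also counted after adjusting over the list alone. The groups, model, contrasts, threshold, lists, the rule for named genes and the alternatives were set before the data were examined, apart from those said to be chosen after.

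The rule for named genes took the 10 highest and 10 lowest log2 fold changes among called genes of the 4F comparison, and 5 each for the other contrasts, with a mean of at least 1 CPM, arms that do not overlap and a symbol that is not a predicted, clone or pseudogene name. With all libraries it named no gene, so besides the OSKM factors the genes named were chosen after their values were seen: list members from the up to 4 with the smallest p, genes called by DESeq2 or called without 1 skin library, and genes that mark a library. The rule was also applied to the DESeq2 calls, so for genes it took there the lack of overlap between arms was fixed by the choice.

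Alternatives changed 1 choice at a time: DESeq2's size factors in edgeR, no filter on low counts, no sex term, the libraries of 1 genotype, 4F females alone beside the B6 libraries, DESeq2, and each library left out in turn. With 1 male per 4F arm and sex in the model, leaving out either 4F male leaves the females compared, so these 2 fits differ little beyond the genes kept. After seeing the data, 6 libraries with transcripts of another tissue, the other sex or an extreme cell composition were left out as a further alternative: untreated 4F skin replicate 1, muscle replicate 3, lung replicate 2 and spleen replicate 2, and untreated B6 liver and spleen replicate 2. All 6 were untreated, so this choice is one-sided by arm. Treated libraries with transcripts of another tissue stayed in. Among these were 4F muscle replicate 2, with 24.1 CPM of the liver gene Apoc3, and B6 spleen replicate 2, with 17.7 CPM of the pancreas gene Clps. The other groupings of the 6 4F libraries of each tissue were fitted in the same way. Genes shared over tissues were compared with 1000 shuffles of the calls.

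The steps were tested on simulated data in which 200 genes per tissue were changed 2-fold or 4-fold in the 4F or B6 libraries. For the 4F contrast edgeR recovered 62, 0, 7, 12, 0 and 1 of 100 genes changed 2-fold in kidney, liver, lung, muscle, skin and spleen, and 94, 31, 62, 70, 2 and 58 of 100 genes changed 4-fold, and called at most 10 unchanged genes. DESeq2 called 39 to 80 unchanged genes in the same data. The spread between replicates exceeded counting noise in all 48 pairs of replicates, with a chi-square per degree of freedom of 12.5 to 894.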

Results

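Total RNA was sequenced from skin, kidney, lung, liver, spleen and skeletal muscle of aged mice, in 60 libraries. The 4F mice carry 1 copy of a doxycycline-inducible cassette of the reprogramming factors Pou5f1 (Oct4), Sox2, Klf4 and Myc, together called OSKM, and 1 copy of the rtTA transactivator that doxycycline switches on. Treated 4F mice drank doxycycline at 1 mg/ml on 2 days of each week, with 5 days off, for 10 months from 12 to 22 months of age; their controls were untreated 4F mice of 22 months. Each tissue had 3 treated and 3 untreated 4F libraries, with 1 male and 2 females in each arm. C57BL/6 mice without the cassette, called B6 here, received doxycycline for 5 months, from 20 to 25 months of age, and stood against untreated B6 mice, with 2 male libraries per arm and tissue. Library totals ran from 18517963 to 43176392 counts. The labels do not state that the libraries of a tissue come from separate animals, so p-values below measure the spread between samples.

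Female libraries held 312 to 1918 CPM (counts scaled to library size) of Xist, the RNA that silences an X chromosome, and male libraries at most 9.96, apart from untreated 4F muscle replicate 3, a male, which held 163. Untreated 4F skin replicate 1, labelled female, held 8.71 CPM of the Y-linked Ddx3y beside 680 CPM of Xist, while the other female libraries held at most 0.232 CPM of Ddx3y. All other libraries carried the transcripts of their labelled sex.

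The cassette's factors were the first thing examined, since they show whether induction is visible in the RNA. Pou5f1 (ENSMUSG00000024406), the factor that normal adult tissues lack, was nearly absent. Its highest level was 0.229 CPM, or 8 counts, in treated 4F skin replicate 2, and 48 of the 60 libraries held no count. Sox2, which marks airway and some skin cells, was tested in lung, with 12.3 ± 4.32 CPM in treated and 17.9 ± 3.75 CPM in untreated 4F libraries (SD, n = 3 each), and in skin, where it stayed near the detection limit with a log2 fold change of 0.03 ± 0.85 (SE). Klf4, a regulator of epithelial differentiation, and Myc, a driver of growth, were tested in all 6 tissues, and neither passed the threshold in any. Myc in liver had the lowest unadjusted p of these (0.00411), at 25.4 ± 12.9 CPM in treated against 8.53 ± 1.90 CPM in untreated 4F libraries (log2 fold change 1.42 ± 0.35), with an adjusted p of 1; the lowest adjusted p was 0.464, for Myc in skin (log2 fold change -0.76 ± 0.45), where the change was -0.17 without untreated replicate 2. In liver, untreated B6 livers held 30.5 CPM. Small log2 fold changes crossed 0 with the loss of 1 library, given here for the library that took each furthest: Klf4 in kidney was -0.0074 without untreated replicate 3, in lung -0.10 without treated replicate 3 and in muscle 0.25 without treated replicate 3. The same held for Myc in kidney, at -0.014 without treated replicate 3, for Myc in lung, at -0.067 without untreated replicate 2, and for Sox2 in skin, at -0.53 without untreated replicate 1. Reads of the cassette and of the mouse's own copies of these genes cannot be separated in gene counts, and the time between the last doxycycline days and sampling was not given in the sources used here.

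**Figure D1:**
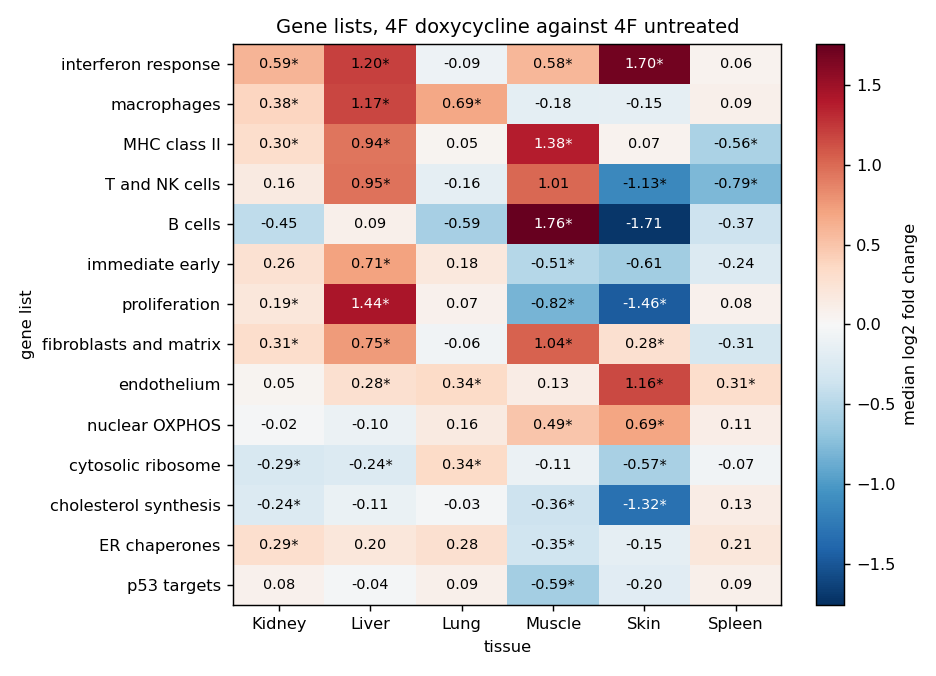
Median log2 fold change over the tested members of 14 gene lists (vertical axis) in the 6 tissues (horizontal axis), 4F doxycycline against 4F untreated, as colour and printed value; an asterisk marks a call by camera with its preset correlation. No list was called with an estimated correlation; the interferon median was 0.59 in kidney, 1.20 in liver, 0.58 in muscle and 1.70 in skin, against -0.09 in lung and 0.06 in spleen.

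In the 4F kidney, doxycycline-treated mice held more transcripts of antiviral interferon-response genes and of protein-folding chaperones, and fewer of plasma cells and ribosomal proteins. Of 22 interferon genes tested, 21 were higher, with a median log2 fold change of 0.59. Irf7, the transcription factor that amplifies the interferon response, held 42.4, 41.8 and 44.2 CPM in the 3 treated libraries against 20.7, 14.7 and 28.1 CPM in the untreated ones (log2 fold change 1.05 ± 0.24), and Ifit1, which binds viral RNA, differed by 0.82 ± 0.19. All 11 chaperones of the endoplasmic reticulum (ER) were higher, with a median of 0.29, among them Herpud1, a part of the ER degradation machinery, at 724 ± 73.3 against 493 ± 111 CPM (SD, n = 3 each). Plasma cell genes had a median of -0.45, with 3 of 15 higher; Iglc2, a light chain constant region, differed by -1.21 ± 0.30 and Jchain, which joins antibody units, by -1.11 ± 0.39 (-0.71 without untreated replicate 2 or treated replicate 3). Macrophage genes had a median of 0.38, and 12 of 14 were higher. Clock genes driven from E-boxes had a median of 0.15, with Ciart, a repressor of the circadian clock, at 27.1 ± 3.35 against 11.4 ± 6.87 CPM (log2 fold change 1.40 ± 0.32).

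These kidney lists were called by camera with its preset correlation, and none held with an estimated correlation: adjusted p = 0.541 with an estimated correlation for the interferon, chaperone, plasma cell, ribosome and clock lists, and 0.543 for macrophages. Gene by gene, edgeR called 0 of 18092 genes in 4F kidney, with 928 at an unadjusted p under 0.05 against 904.6 by chance. DESeq2 called 16, of which 7 were higher and 9 lower. In the simulated 4F changes DESeq2 called 39 to 80 unchanged genes per tissue. Its adjusted p-values, here and in the other tissues, are therefore not held to an error rate of 0.05. Adjusted over the list alone, 8 interferon members, 2 chaperones and 1 plasma cell gene passed, against 0 adjusted over all genes. The DESeq2 calls included Alas1, the first enzyme of heme synthesis (0.65 ± 0.13, DESeq2 adjusted p 0.00732), and Hlx, a homeobox factor (-1.20 ± 0.24, DESeq2 adjusted p 0.0268). Both met the rule for named genes, which takes only arms that do not overlap. With 1 male in each 4F arm and sex in the model, leaving out either male (treated replicate 1 or untreated replicate 3) leaves the females compared, so in each tissue these 2 fits are nearly 1 test. In kidney, untreated replicate 2 carried much of these medians: without it the interferon median was 0.34, the chaperone median 0.18, the ribosome median -0.09 in place of -0.29 (camera adjusted p 0.113) and the plasma cell median -0.16 (0.474). The plasma cell call also ended without treated replicate 3 (median -0.35, 0.0811) and its median was -0.96 without either male and -0.76 without untreated replicate 1. Without untreated replicate 1 the ribosome median was -0.43 and the macrophage and clock calls ended (0.27, 0.231, and 0.09, 0.427). Other fits raised these 2 medians, the macrophage median to 0.61 or 0.60 without either male and the clock median to 0.30 without untreated replicate 2 and 0.25 or 0.24 without either male.

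In the 4F liver, transcripts of interferon-response, immediate early, macrophage, matrix and cell division genes were higher in treated mice. All 22 interferon genes were higher, with a median log2 fold change of 1.20; Usp18, which damps interferon signalling, stood at 27.5 ± 6.25 against 9.48 ± 3.76 CPM (SD, n = 3 each), and Irf7 differed by 1.53 ± 0.38. Immediate early genes, which respond to stimuli within minutes, had a median of 0.71 with 12 of 14 higher. Their largest contributor, Jun, a subunit of the AP-1 transcription factor, held 97.6, 77.4 and 119 CPM in treated against 33.1, 23.9 and 36.3 CPM in untreated libraries, and Egr1 differed by 1.28 ± 0.28. Macrophage genes had a median of 1.17 with 14 of 14 higher, matrix genes 0.75 with 17 of 18 and cell division genes 1.44 with 19 of 20. Neutrophil genes had a median of 1.475, megakaryocyte genes 1.47, T and NK cell genes 0.95 and MHC class II genes 0.94, against 0.09 for B cell genes. Marco, a scavenger receptor of macrophages, held 124 ± 53.1 against 31.1 ± 8.0 CPM.

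In 4F liver edgeR called 0 of 16292 genes, with 291 at an unadjusted p under 0.05 against 814.6 by chance. DESeq2 called 7, among them Jun (DESeq2 adjusted p 0.000522), Usp18 (0.0128) and Marco (0.00222). In the simulated 4F liver data 64 of its 156 calls were unchanged genes. Jun, Usp18 and Marco met the rule for named genes, which takes only arms that do not overlap. Camera with its preset correlation called 13 of 40 lists, 12 of them higher, and none with an estimated correlation: adjusted p = 0.362 with an estimated correlation for interferon and 0.128 for immediate early genes. When adjusted over the list alone, 2 interferon and 2 immediate early members passed, against 0 adjusted over all genes. The interferon median was 0.75 without untreated replicate 2 and 1.83 without untreated replicate 1. Without treated replicate 3 the matrix median was 0.36 and the macrophage median 0.77, without either male the matrix median was 1.15, and without untreated replicate 2 the cell division median was 0.81.

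In the 4F lung, treated libraries held more transcripts of stress-response, ribosomal protein and macrophage genes, and almost none of the skeletal muscle transcripts seen in untreated lungs. All 10 skeletal muscle genes were lower, with a median log2 fold change of -6.20. Acta1, the actin of skeletal muscle fibres, held 5.55, 1491 and 4.77 CPM in untreated and 0.39, 0.34 and 0.64 CPM in treated libraries, and Myh4, a fast myosin, had no count in any treated library against 6.68, 67.8 and 7.87 CPM; with Myh4 at its bound, 3 counts over the treated arm, the list median stays at -6.20. In B6 lungs Myh4 varied between the libraries of each arm, at 0.45 and 32.2 CPM in treated and 9.68 and 0.45 CPM in untreated ones. Genes of the integrated stress response, which adjusts translation and amino acid supply, had a median of 0.41 with 14 of 15 higher, including Trib3 at 0.58 ± 0.20. Cytosolic ribosomal protein genes had a median of 0.34 with 23 of 26 higher, macrophage genes 0.69 with 13 of 14 and endothelial genes 0.34. Treml4, a receptor of circulating monocytes, held 68.8 ± 37.4 against 11.5 ± 9.85 CPM, S1pr5, which guides lymphocyte and monocyte exit into blood, 23.6 ± 8.37 against 6.28 ± 3.92 CPM, and Adrb1, the beta-1 adrenergic receptor, 58.8 ± 10.9 against 27.2 ± 9.05 CPM. The interferon list was not called, with a median of -0.09, and turned on single libraries: it was called higher without untreated replicate 1 (median 0.65, camera adjusted p 0.00426) and lower without untreated replicate 2 (-0.43, 0.000227), neither with an estimated correlation.

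In 4F lung edgeR called 0 of 19289 genes, with 1165 at an unadjusted p under 0.05 against 964.4 by chance. DESeq2 called 37, of which 11 were higher, Adrb1 (DESeq2 adjusted p 0.00085), S1pr5 (0.00847) and Treml4 (0.0243) among them. The genes named here met the rule that takes only arms that do not overlap. Camera with its preset correlation called 10 of 42 lists, and each had an adjusted p = 0.894 with an estimated correlation. In all, 7 skeletal muscle genes passed when adjusted over the list alone, against 0 adjusted over all genes. Without untreated replicate 2 the skeletal muscle median was -1.72 and the ribosome median 0.20, and the macrophage call ended (median 0.34, camera adjusted p 0.125), as it did without treated replicate 2, where its sign turned (-0.03, 0.507), while its median was 1.15 without either male. The endothelial call ended without treated replicate 3 (0.14, 0.222) and without untreated replicate 1 (0.19, 0.251).

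In the 4F skeletal muscle, treated mice held more transcripts of extracellular matrix, complement, mitochondrial respiration and interferon genes, and fewer of p53 and NF-kB target genes. All 19 matrix genes were higher, with a median log2 fold change of 1.04, as were all 12 complement genes (median 0.97) and all 16 nuclear genes of oxidative phosphorylation (median 0.49). Genes of slow fibres, which are rich in mitochondria, were higher with them, 8 of 8 with a median of 1.53, against 0.19 for genes of fast fibres, which were not called. Eln, the gene of elastin, differed by 1.09 ± 0.17 and Serping1, the inhibitor of complement C1, by 0.94 ± 0.17, while C1s1, a C1 protease, stood at 39.9 ± 4.58 against 20.0 ± 5.52 CPM (SD, n = 3 each). Interferon genes had a median of 0.58 with 20 of 22 higher, and Irf7 held 12.8, 9.51 and 7.09 CPM in treated against 4.47, 3.29 and 4.98 CPM in untreated libraries. Of 15 p53 targets only 4 were higher (median -0.59), and Bbc3, a trigger of cell death, differed by -1.34 ± 0.33. Of 17 NF-kB targets 2 were higher (median -0.66). Pim1, a survival kinase, stood at 7.66 ± 0.442 against 25.2 ± 6.37 CPM and Bcl2l11, which promotes cell death, at 6.59 ± 2.15 against 34.5 ± 30.5 CPM. Liver transcripts also differed, with a hepatocyte median of 3.34 and Apoc3 at 0.17, 24.1 and 8.43 CPM in treated against 0.04, 2.17 and 0.02 CPM in untreated libraries, and so did fat and B cell transcripts, with medians of 1.18 and 1.76.

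A single gene passed the edgeR threshold in any 4F tissue. Rplp0-ps1 (ENSMUSG00000081640), a processed pseudogene of the ribosomal protein gene Rplp0, was lower in treated muscle by a log2 fold change of -8.03 ± 0.53 (adjusted p 0.00595). It held 20.6 and 29.8 CPM in the untreated females, but 0.0207 CPM in the untreated male, 0.0893 and 0.0864 CPM in the treated females and no count in the treated male, so its level divided the untreated libraries by sex. Its call ended without treated replicate 2 (adjusted p 0.358), without treated replicate 3 (0.329) and without a sex term (0.643); over its alternatives the adjusted p ran from 1.2e-20 by DESeq2 to 0.643. Without either untreated female the gene failed the filter on low counts and gave no value. In the other 5 tissues the same division of libraries was present.

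**Figure D2:**
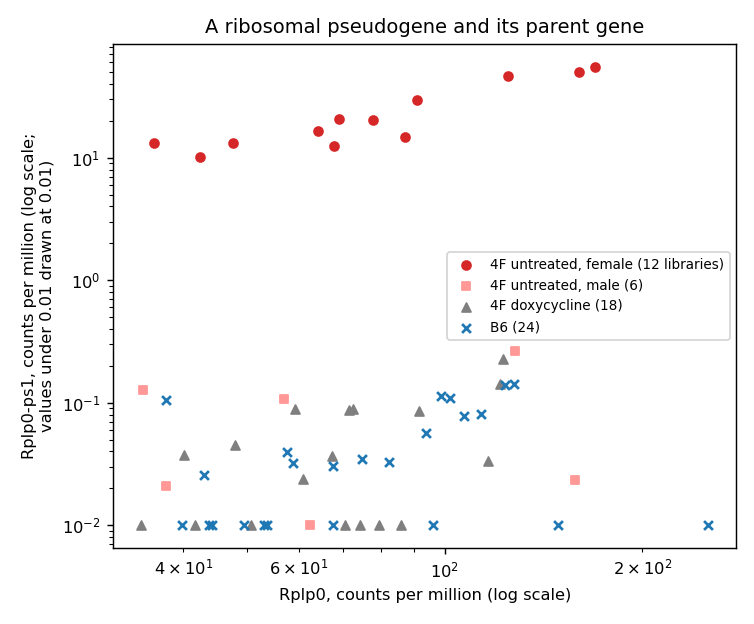
Rplp0-ps1 against its parent gene Rplp0 in every library of the 6 tissues, both in CPM on log axes, 1 point per library, with Rplp0-ps1 values under 0.01 drawn at 0.01. The 12 untreated 4F female libraries hold 10.2 to 55.2 CPM of Rplp0-ps1 and the other 48 libraries at most 0.264 CPM.

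Gene by gene, 1510 of 16427 muscle genes had an unadjusted p under 0.05, against 821.4 by chance. DESeq2 called 80, of which 65 were higher, Eln (DESeq2 adjusted p 0.000688), Serping1 (0.00209) and Irf7 (0.031) among them. Camera with its preset correlation called 23 of 40 lists, 14 of them higher, and none with an estimated correlation: adjusted p = 0.441 with an estimated correlation for matrix and slow fibres and 0.442 for NF-kB targets. The p53 targets were the only list of the 4F comparisons that fry called (adjusted p 0.0431), and this call ended with any 1 of the 6 4F libraries left out, at 0.0922 to 0.325. Adjusted over the list alone, 5 complement, 3 p53, 2 interferon, 1 matrix and 1 NF-kB member passed, against 0 adjusted over all genes. Compared among females, which is what leaving out either male leaves, the lower lists shrank: the NF-kB median was -0.11 without treated replicate 1 (camera adjusted p 0.953) and -0.09 without untreated replicate 3 (0.918), the p53 median -0.25 and -0.22, and the complement median rose to 1.69 and 1.72. These fits do not tell the 2 males apart. The B cell median was 2.76 without treated replicate 1, and the NF-kB median -1.07 without untreated replicate 1. Without untreated replicate 2 the interferon median was 0.37 and the hepatocyte median 5.79. Untreated replicate 3, the male with 163 CPM of Xist, also held 2435 CPM of Spp1 and 2183 CPM of Gpnmb, products of macrophages in damaged tissue, against at most 6.92 and 10.7 CPM in the other 4F muscle libraries.

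In the 4F skin, treated mice held more interferon, endothelial and mitochondrial transcripts and fewer transcripts of cell division, cholesterol and fatty acid synthesis, keratinocytes, hair follicles and sebaceous glands. All 22 interferon genes were higher, with a median log2 fold change of 1.70. Oas2, a sensor of double-stranded RNA, stood at 56.4 ± 12.6 against 8.69 ± 7.08 CPM (SD, n = 3 each), Mx2, annotated as a polymorphic pseudogene, differed by 2.21 ± 0.57, and Irf7 by 1.80 ± 0.54. None of 20 cell division genes was higher (median -1.46), and Mki67, the Ki-67 antigen of cycling cells, differed by -2.17 ± 0.50. None of 15 cholesterol synthesis genes was higher (median -1.32), with Lss, lanosterol synthase, at -1.43 ± 0.30, and 3 of 10 lipogenesis genes were higher (median -0.58), with Acly, which makes acetyl-CoA for fat synthesis, at 94.5 ± 50.1 against 191 ± 43.7 CPM. None of 11 hair follicle genes (median -2.62) and none of 7 sebaceous gland genes (median -2.56) was higher. Tchh, a protein of the growing hair sheath, differed by -2.27 ± 0.56, with 3232 CPM in the untreated male against 562 CPM in the treated one, and 3.32 and 5.53 CPM in the untreated females against 1.40 and 0.57 CPM in the treated ones. Basal keratinocyte genes had a median of -1.77, with Krt14, the keratin of the basal layer, at 179, 2159 and 2648 CPM in untreated and 636, 316 and 84.0 CPM in treated libraries. All 11 endothelial genes (median 1.16) and all 13 mitochondrially encoded genes (median 1.18) were higher. Among the latter, mt-Atp6 stood at a low level, with 6.84, 26.8 and 9.21 CPM in treated and 6.86, 2.58 and 3.32 CPM in untreated libraries. Its log2 fold change of 1.64 was 1.00 without treated replicate 2.

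The skin result depended on untreated replicate 1, the library with Y-linked transcripts, which also held kidney transcripts. With all libraries edgeR called 0 of 18596 genes, with 2314 at an unadjusted p under 0.05 against 929.8 by chance. DESeq2 called 524, of which 144 were higher. Leaving out untreated replicate 1, a comparison chosen after seeing the data, kept untreated replicates 2 and 3. By genes at an unadjusted p under 0.05, replicate 2 was the 4F female set furthest apart in every tissue. In this comparison edgeR called 692 genes, of which 363 rose and 329 fell. Among those that rose were the interferon-induced Ifi44 (4.25 ± 0.48, adjusted p 0.0354), Mx1 (4.30 ± 0.60), Ifit1 (3.86 ± 0.58), Oasl1 (3.75 ± 0.42) and Slfn1 (4.50 ± 0.55). Among those that fell were the keratinocyte genes Slurp2 (-4.23 ± 0.34), Sox15 (-4.01 ± 0.77) and Krt6a (-3.72 ± 0.70), the last a keratin of wounded and hair follicle epithelium. The rule that named these genes takes only arms that do not overlap, so it fixed that all 3 treated libraries lie on 1 side of both remaining untreated ones. The keratinocyte genes also rest on untreated replicate 2, 1 of those 2: with that library left out in place of replicate 1, Slurp2 was -1.70, Sox15 -1.35 and Krt6a -0.79. Among the females the interferon genes were lower than with all libraries, Ifi44 at 1.17 in place of 2.30 and Oasl1 at 0.57 in place of 1.68. Slfn1 stood at 0.40 in place of 1.72, Mx1 at 1.63 in place of 2.59 and Ifit1 at 1.34 in place of 2.47. Without untreated replicate 1, 19 of the 22 interferon genes passed over all genes, and the list's fry adjusted p was 0.0381. Its camera adjusted p in that fit was 0.416 with an estimated correlation. Matrix genes, with a median of 0.28 over all libraries, had a median of 2.18 without it but -0.18 without untreated replicate 2 and -0.12 without either male, and complement genes 2.25 in place of 0.43.

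**Figure D3:**
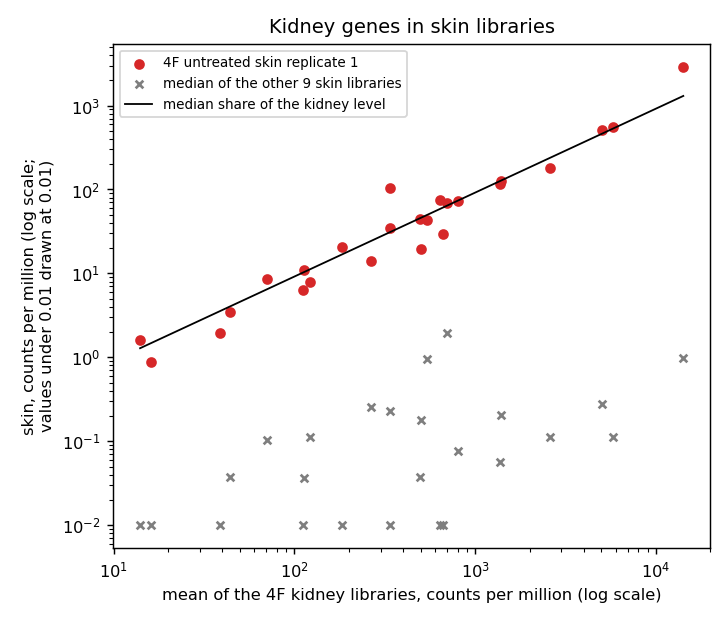
Levels of 25 kidney genes in untreated 4F skin replicate 1 (circles) and their median in the other 9 skin libraries (crosses), against their mean in the 4F kidney libraries, in CPM on log axes, with values under 0.01 drawn at 0.01. The line marks the median share of the kidney level in that library, 9.18%.

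With all libraries in, camera called 21 of 43 skin lists with its preset correlation, 10 of them higher, and none with an estimated correlation: adjusted p = 0.585 with an estimated correlation for the interferon, cell division, endothelial, cholesterol, lipogenesis, hair follicle, sebaceous and mitochondrially encoded lists, and 0.655 for basal keratinocytes. Adjusted over the list alone, 12 cell division, 8 cholesterol, 5 lipogenesis, 4 sebaceous, 1 hair follicle and 1 interferon member passed, against 0 adjusted over all genes. Single libraries moved several medians. Without untreated replicate 1 the interferon median was 3.11 and the endothelial median 1.83, and among the females, which is what leaving out either male leaves, the interferon median was 0.86. Without untreated replicate 2 the sebaceous median was -0.91, the mitochondrially encoded median 0.77, and the basal keratinocyte call ended (-0.28, camera adjusted p 0.486).

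**Figure D4:**
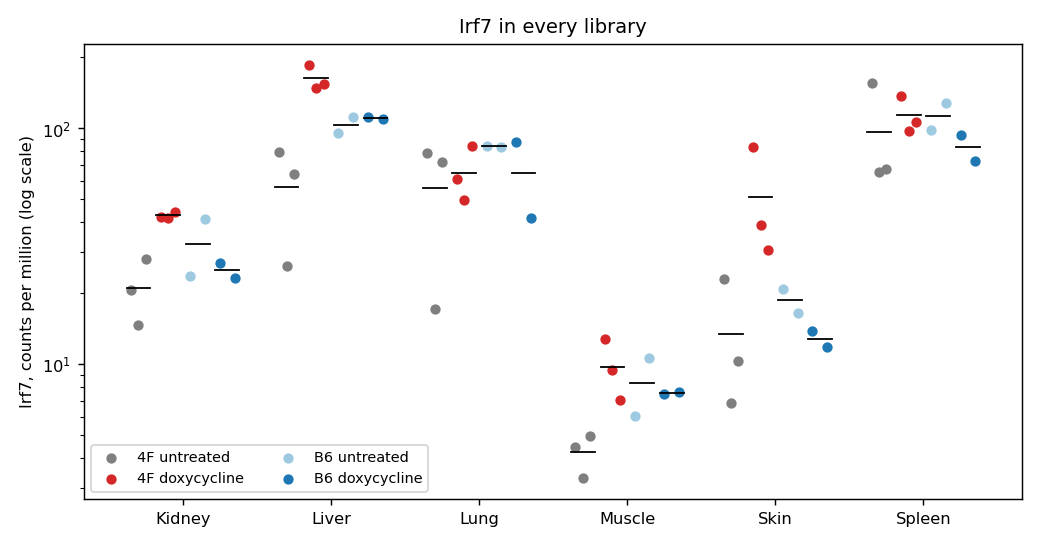
Irf7 in CPM (log axis) in each library of the 6 tissues, 1 point per library, with a bar at the mean of each arm. In kidney, liver, muscle and skin every treated 4F library lies above every untreated 4F library. The B6 libraries, at 6.02 to 10.6 CPM in muscle and 95.7 to 112 CPM in liver, also lie above the untreated 4F ones there (at most 4.98 and 79.2 CPM). In kidney and skin the B6 and untreated 4F libraries overlap.

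In the 4F spleen, treated mice held fewer transcripts of T and NK cells and of antigen presentation by MHC class II, more of red pulp macrophages and megakaryocytes, and almost no transcripts of the exocrine pancreas. None of 16 T and NK cell genes was higher (median log2 fold change -0.79); Ccl5, a chemokine of activated T cells, stood at 102 ± 52.6 against 186 ± 70.1 CPM, and Gzmb, a cytotoxic granule protease, at 3.09 ± 0.803 against 13.5 ± 13.5 CPM (SD, n = 3 each). None of 9 MHC class II genes was higher (median -0.56). All 7 red pulp macrophage genes were higher (median 0.61), and Treml4 differed by 1.20 ± 0.31. All 7 megakaryocyte genes were higher (median 1.52). Siglec1, a receptor of marginal zone macrophages, held 85.0, 74.8 and 54.6 CPM in treated against 32.2, 37.7 and 32.5 CPM in untreated libraries, and Ace, the angiotensin-converting enzyme, 75.7 ± 18.2 against 24.6 ± 5.53 CPM. Cdkn2a, which encodes the cell cycle inhibitor p16 and rises in senescent cells, stood at 5.03 ± 1.73 against 10.1 ± 1.20 CPM. Neither edgeR (adjusted p 0.991) nor DESeq2 (0.396) called it, and in B6 spleens it was higher with doxycycline, at 6.76 against 4.11 CPM. Clps, a cofactor of pancreatic lipase, held 16.9, 487 and 1.42 CPM in untreated libraries and at most 0.0914 CPM in treated ones. The interferon list was not called, with a median of 0.06, but was called higher without untreated replicate 1 (0.42, camera adjusted p 6.1e-05; 0.894 with an estimated correlation).

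In 4F spleen edgeR called 0 of 18574 genes, with 727 at an unadjusted p under 0.05 against 928.7 by chance. DESeq2 called 21, of which 4 were higher. Siglec1 (DESeq2 adjusted p 0.0319) and Ace (0.0149) were called, and both met the rule that takes only arms that do not overlap. Camera with its preset correlation called 10 of 40 lists and none with an estimated correlation: adjusted p = 0.664 with an estimated correlation for T and NK cells, red pulp macrophages and exocrine pancreas, and 0.750 for megakaryocytes and MHC class II. When adjusted over the list alone, 5 pancreas genes and 1 red pulp macrophage gene passed, against 0 adjusted over all genes. Without untreated replicate 2 the megakaryocyte call ended (median 0.73, camera adjusted p 0.0687) and the T and NK cell median was -0.49, with Ccl5 at -0.52 in place of -0.96 and Gzmb at -0.94 in place of -1.74 (Ccl5 was -1.52 without either male); the megakaryocyte median was 0.75 without treated replicate 2 and 2.48 without either male. The red pulp call ended without either male (0.45, 0.0823 and 0.0827). The MHC class II call ended without untreated replicate 1 (-0.42, 0.0518), and its median was -0.31 without treated replicate 3 and -0.89 without either male.

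B6 mice lack the cassette, so their doxycycline comparison concerns the drug without reprogramming factors, here over 5 months and at a greater age. Untreated B6 mice were 25 months old by the labels and 26 months by the series text. The differences below were not shown to come from the drug. In B6 kidney, treated mice held fewer neutrophil transcripts, with a list median of -2.87, and fewer of red cell precursors, with a median of -1.10; Ngp, a neutrophil granule protein, stood at 0.0801 and 0.368 CPM in treated against 8.04 and 11.1 CPM in untreated libraries. In B6 liver and spleen, 1 untreated library in each held most of the difference. In untreated B6 liver replicate 2, Msr1, a macrophage scavenger receptor, held 656 CPM against 19.9 to 28.6 CPM in the other 3, and the macrophage median was -3.10. In untreated B6 spleen replicate 2, Erfe, the hormone of red cell precursors, held 235 CPM against 3.09 CPM in its fellow, and the erythroid median was -3.15. In B6 skin, immediate early genes had a median of -1.93, with Junb, an AP-1 subunit, at 43.7 ± 9.74 against 240 ± 122 CPM (SD, n = 2 each), while nuclear oxidative phosphorylation genes had a median of 1.05. In B6 muscle, Arntl, the clock activator also called Bmal1, stood at 7.61 ± 1.11 against 16.9 ± 1.03 CPM, and nuclear oxidative phosphorylation genes had a median of 0.59. In B6 lung, plasma cell genes had a median of -0.92.

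In B6 mice edgeR called 0 genes in each of the 6 tissues. With simulated B6 changes of 4-fold it recovered 87, 0, 45, 52, 0 and 10 of 100 genes in kidney, liver, lung, muscle, skin and spleen. The counts of 0 in liver, skin and spleen thus exclude little. Genes at an unadjusted p under 0.05 numbered 703 in kidney, 1530 in liver, 68 in lung, 458 higher and 557 lower in muscle, 1464 in skin and 1172 in spleen. Chance alone would give 904.6, 814.6, 964.4, 821.4, 929.8 and 928.7 in the same order. DESeq2 called 35, 49, 2, 2, 68 and 160, again in that order. With simulated B6 changes it called 44 to 65 unchanged genes per tissue. Camera with its preset correlation called 21, 19, 13, 8, 21 and 18 lists and none with an estimated correlation: adjusted p = 0.107 with an estimated correlation for kidney neutrophils, 0.651 for liver macrophages, 0.943 for lung plasma cells, 0.998 for muscle oxidative phosphorylation, 0.434 for skin immediate early genes and 0.725 for spleen erythroid genes. Adjusted over the list alone, 7 neutrophil members in kidney, 10 macrophage members in liver and 10 immediate early members in skin passed. The liver and spleen counts turned on 1 control library, since with replicate 2 as the lone untreated library, assumed to vary like the other groups, edgeR called 6113 genes in liver and 2178 in spleen. With untreated replicate 1 left out in kidney it called 14, and with untreated replicate 2 left out it called 1 each in lung and skin. Without untreated replicate 2 in liver the log2 fold change of Msr1 turned from -3.81 to 0.14.

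The difference between the doxycycline effects of 4F and B6 mice asks what goes beyond the drug, although genotype differed together with age, length of treatment and sex make-up. In kidney, Ngp differed by 7.73 ± 1.24 and Gdf15, a stress-induced hormone, by 2.99 ± 0.53; Gdf15 stood at 17.7 ± 8.54 against 9.86 ± 1.75 CPM in 4F mice and at 14.8 ± 1.83 against 65.4 ± 10.9 CPM in B6 mice (SD, n = 3 and n = 2 each). In spleen, Erfe differed by 10.16 ± 2.56, of which the B6 control library named above was a large part. In skin, Cidea, a lipid droplet protein, differed by -4.04 ± 0.68. Interferon genes differed between genotypes by a median of 0.87 in kidney (adjusted p = 0.312 with an estimated correlation).

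For this difference edgeR called 0 genes in each tissue, with 662, 1617, 166, 647, 605 and 1322 at an unadjusted p under 0.05 in kidney, liver, lung, muscle, skin and spleen. Only liver and spleen lay above the chance counts given for B6 mice. DESeq2 called 21, 17, 1, 38, 65 and 47. In kidney DESeq2 called Ngp (adjusted p 8.4e-08) and Gdf15 (0.00014), and in skin Cidea (0.000119). Camera with its preset correlation called 25, 19, 16, 17, 19 and 17 lists, and none with an estimated correlation. With all libraries the skin difference was 2.02 ± 1.33 for Ifi204, 2.00 ± 1.19 for Trim30a and -5.85 ± 1.84 for Slurp2. Without untreated 4F skin replicate 1 edgeR called 7 genes in skin, of which 2 were higher in the 4F effect, Ifi204 (3.76 ± 0.32) and Trim30a (3.49 ± 0.27), both interferon-induced, and 5 were lower, among them Slurp2 (-6.44 ± 0.50) and Cidea (-4.37 ± 0.41). With B6 untreated replicate 1 left out, it called 5672 genes in liver and 5 in kidney, and with B6 untreated replicate 2 left out 1 in lung.

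Across tissues, 3 lists were called higher in 4 tissues each of the 4F comparison by camera with its preset correlation, and no list kept its call with an estimated correlation. Matrix genes were called in kidney (median 0.31), liver, muscle and skin, and endothelial genes in liver (0.28), lung, skin and spleen (0.31); the kidney matrix call ended without untreated replicate 1 (0.31, camera adjusted p 0.407) and its median was 0.15 without untreated replicate 2 and 0.53 or 0.52 without either male, the liver endothelial call ended with any 1 of 5 of the 6 4F libraries left out (0.0616 to 0.109), and the spleen endothelial call ended without untreated replicate 1 (0.25, 0.246) and without either male (0.16, 0.195 and 0.188), with a median of 0.52 without treated replicate 2 and 0.72 without untreated replicate 2. Interferon genes were called in kidney, liver, muscle and skin, where each call held with every single 4F library left out, and in neither lung nor spleen. Whether lung and spleen stand apart depends on 1 library, since without untreated replicate 1 the list was called higher in both (medians 0.65 and 0.42) and without untreated replicate 2 it was called lower in lung (-0.43). No gene passed the edgeR threshold in the same direction in 3 or more tissues. By DESeq2 3 genes did, Irf7, Rplp0-ps1 and Gm14165, another copy of a ribosomal protein gene, where shuffled calls gave a mean of 0.002. The shuffles treat the tissues as independent, which the libraries of 1 replicate number may not be. Gm14165 divided the libraries as Rplp0-ps1 did, with 1.46 to 9.56 CPM in the 12 untreated 4F female libraries and at most 0.503 CPM in the other 48. The sharing of these 2 genes over tissues therefore need not reflect doxycycline. Across genes, the 4F and B6 effects had Pearson correlations of -0.025 in kidney, -0.48 in liver, 0.077 in lung, -0.046 in muscle, 0.36 in skin and -0.32 in spleen, and Spearman correlations of 0.096, -0.41, 0.13, 0.23, 0.40 and -0.32; genes are not independent replicates, so these describe the effects without testing them. With single libraries left out, a choice made after seeing the data, the correlation ran from -0.16 to 0.13 in kidney, -0.19 to 0.27 in lung, -0.23 to 0.12 in muscle and -0.42 to -0.11 in spleen. The liver correlation was 0.15 without untreated B6 replicate 2, and the skin correlation 0.13 without untreated B6 replicate 2.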

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

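Of the tests in this part, the groupings of all 6 4F libraries of a tissue were planned; the tests of explanations and the groupings of 5 skin libraries were chosen after the result was seen.

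In 28 cases camera with its preset correlation called a gene list in opposite directions in 4F and B6 mice, and also called the difference of the doxycycline effects. The medians of these lists were opposite as well. None of the 28 held with an estimated correlation, where the adjusted p ran from 0.165 to 0.775. The values are the median over list members of the 4F effect minus the B6 effect, on the log2 scale. In kidney, more in the 4F than in the B6 effect were neutrophil genes by 3.57, cell division genes by 1.29, macrophage genes by 1.15, adipocyte genes by 0.93, interferon genes by 0.87, integrated stress response genes by 0.62 and fatty acid oxidation genes by 0.36, while cholesterol synthesis genes differed by -0.36. In liver the differences were 6.29 for neutrophils, 4.23 for cell division, 4.16 for macrophages, 4.08 for megakaryocytes, 4.06 for MHC class II, 2.83 for matrix, 2.53 for T and NK cells, 2.29 for senescence and secreted inflammatory factors and 2.18 for immediate early genes, and untreated B6 liver replicate 2, with 656 CPM of Msr1 against 22.1 CPM in its fellow, enters each of them. In lung, cytosolic ribosome genes differed by 0.42, heat shock genes by 0.58, mitochondrial ribosome genes by 0.29 and skeletal muscle genes by -7.41. In muscle, hepatocyte genes differed by 6.15. In skin, endothelial genes differed by 1.73 and sebaceous gland genes by -4.76. In spleen, exocrine pancreas genes differed by -15.92, T and NK cell genes by -1.36, MHC class II genes by -1.25 and red pulp macrophage genes by 1.04; pancreas lies next to the spleen, and Clps in untreated 4F spleen replicate 2 was 487 CPM. The lung skeletal muscle list and the spleen pancreas list each had 1 member with no count in an arm; with that member at its bound, 3 counts over the arm, the medians stay at -7.41 and -15.92.

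Interferon genes were higher in treated 4F kidney, liver, muscle and skin, and tests that left out libraries argue against a single library as the source: over 24 such fits, of which the 2 per tissue without a male are nearly 1 test of the females, the lowest list median was 0.34, and camera with its preset correlation called the list in all 24, with a highest adjusted p of 0.00245, though in none of them with an estimated correlation (adjusted p 0.111 to 0.863). Untreated replicate 2 still carried part of it, since without that library the median was 0.34 in place of 0.59 in kidney, 0.75 in place of 1.20 in liver and 0.37 in place of 0.58 in muscle, and among the females alone, which is what leaving out either male leaves, it was 0.86 in place of 1.70 in skin. More immune cells may account for the liver, where 3 of the 4 immune cell lists had a median of at least 0.60, midway between 0 and the interferon median, but in kidney and muscle 3 of 8 list medians reached that midpoint, which leaves it open there. In muscle without untreated replicate 3, which leaves the females compared, the macrophage, B cell, neutrophil and T and NK cell medians were 1.53, 1.53, 0.87 and 0.66. The interferon median in that fit was 0.85, so each list passed its midpoint and more immune cells may account for muscle too. In skin the highest upper quartile of the 4 lists was 0.38, under the midpoint of 0.85, yet without untreated replicate 1 the macrophage median was 1.62 against a midpoint of 1.56, so immune cells cannot be excluded there either. The highest interferon median in B6 mice was -0.14, but the difference between genotypes had an adjusted p of 0.312, 0.624, 0.659 and 0.497 with an estimated correlation in kidney, liver, muscle and skin, and B6 mice were older and treated for a shorter time, so an effect of doxycycline itself cannot be told apart from one of the cassette. A response to the reprogramming factors remains a hypothesis that the design did not separate from these.

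Rplp0-ps1, the gene called in 4F muscle, held 10.2 to 55.2 CPM in the 12 untreated 4F female libraries and at most 0.264 CPM in the other 48. Absence of doxycycline alone and female sex alone are excluded, since untreated 4F males held at most 1.12% and treated 4F females at most 0.474% of the untreated female mean of the tissue. Reads of Rplp0 counted for this copy at 1 rate in all libraries are also excluded as the whole source. The ratio of Rplp0-ps1 to Rplp0 was at most 0.00366 in the other 48 libraries, with 34.5 to 252 CPM of Rplp0, against 0.168 to 0.370 in the 12. Such counting confined to the 12 libraries is not excluded by these ratios. Among the 12 the ratio varied 2.20-fold, where the level of Rplp0-ps1 varied 5.39-fold. Gm5948, which shares 1.10% of its 25-base words with Rplp0 where Rplp0-ps1 shares 30.5%, had the same division, with 1523 counts in the 12 libraries and 10 in the other 48. Gm14165, which shares 46.55%, had it too, with 1698 counts in the 12 and 115 in the other 48. The 12 libraries carry the numbers of 2 adjoining blocks of 6 libraries, 1 block per untreated female replicate, so a variant carried by these animals, such as a further copy of the gene, and a handling difference of these blocks remain open and untested. The muscle call therefore need not reflect doxycycline.

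Untreated 4F skin replicate 1, labelled female, held transcripts of kidney and of the Y chromosome. RNA of a male kidney in this library may be the source, since 25 kidney genes stood at a median of 9.18% of their 4F kidney level, 21 of them within 2-fold of that median, and 4 Y-linked genes at 13.7% to 15.7% of their male kidney level. A kidney sample labelled skin is excluded, since Krt5, the keratin of basal skin cells, held 384 CPM against 155 CPM in the lowest other skin library. Xist at 680 CPM shows that female tissue was present as well. No biological explanation was tested, and whether the mixing arose at dissection, extraction or library preparation stays open.

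The 6 4F libraries of a tissue form 10 groupings of 3 and 3, too few for a share under 0.05. The real grouping gave 0 genes in kidney, liver, lung, skin and spleen, so all 10 groupings gave as many there, and 1 in muscle, matched in 1 of 10 groupings, itself; the highest of the others gave 776, 3, 22, 43, 5 and 0. In kidney the highest count came from the grouping of treated replicate 1 with untreated replicates 2 and 3. Both males fall on 1 side of it, so with sex in the model it sets 1 library, untreated replicate 2, against 3 females, with the spread taken from the other groups, a fit of another form than the real one; the other 3 groupings of its form gave 0 genes each in kidney. Within its form this grouping sets untreated replicate 2 apart from the other kidney females. Counts from fits of different form cannot be compared, so no conclusion on treatment is drawn from them. For skin without untreated replicate 1 the 692 genes were matched by 1 of 9 fitted groupings, the real one, and the highest of the others gave 0; these too are too few for a share under 0.05.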

How the results depend on the processing

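Leaving out the libraries doubted, single libraries for gene lists and correlations, and single B6 libraries for the 4F count were chosen after seeing the data. No paired analysis was possible because no label pairs libraries across arms. Of 1622 log2 fold changes of named genes under alternatives 1467 kept their direction and their side of the threshold. Another 132 were past it only under the alternative, 3 were no longer past it and 20 turned. The main fits called 1 gene, so keeping a side mostly means staying uncalled. Many genes were named because an alternative called them, so these counts do not measure robustness. Size was not counted: Krt5 in 4F skin went from -2.36 to -0.60 without untreated replicate 2. Of 493 list medians 399 were kept, 90 lost their call and 4 turned. The 2 fits that leave out a 4F male are both comparisons of the females and count as 2 in these numbers. At least 1 left-out library ended or turned the call of 20 of the 50 lists named for 4F mice. The cause of the differences given here was not tested, except that leaving out libraries lowers their number. At 3 or 2 libraries per arm, recovery of simulated 2-fold changes by edgeR was 0 of 100 in 4F liver and skin, so the counts of 0 there do not exclude changes of that size.

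Without a filter on low counts the 4F comparison gave 288 genes in kidney, 2 in liver, 2 in lung, 16 in muscle and 1 in spleen, the B6 comparison 427 in kidney, and the difference 370 in kidney and 1 in lung. DESeq2 gave 16, 7, 37, 80, 524 and 21 genes for 4F mice in kidney, liver, lung, muscle, skin and spleen, 35, 49, 2, 2, 68 and 160 for B6 mice and 21, 17, 1, 38, 65 and 47 for the difference. In muscle the 4F count was 0 without a sex term and 0 from the 4F libraries alone, and in kidney 1 with females only. Without the doubted libraries the 4F count was 1 in liver and 692 in skin, and the difference 7 in skin. Genes past the threshold in 3 or more tissues were 2 without a filter, Rplp0-ps1 and Gm5948, and 3 by DESeq2. Apart from Irf7, these genes set the untreated 4F females apart from the other libraries. With an estimated correlation 0 lists were called in each of the 6 tissues.

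With single 4F libraries left out the 4F count ran from 0 to 1 in kidney, 0 to 0 in liver, lung and spleen, 0 to 1 in muscle and 0 to 692 in skin; with single B6 libraries left out it changed in liver alone, to 1 without untreated replicate 2. The B6 count, with single B6 libraries left out, ran from 0 to 14 in kidney, 0 to 6113 in liver, 0 to 1 in lung and skin, 0 to 0 in muscle and 0 to 2178 in spleen. The difference, with single libraries of either genotype left out, ran from 0 to 5 in kidney, 0 to 5672 in liver, 0 to 1 in lung, 0 to 7 in skin and 0 to 0 in muscle and spleen. Lists called in 4F mice, with single 4F libraries left out, ran from 9 to 22 in kidney, 11 to 14 in liver, 9 to 15 in lung, 20 to 26 in muscle, 17 to 25 in skin and 9 to 14 in spleen.

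The correlation of the 4F and B6 effects without a filter was -0.157 in liver, 0.147 in skin and -0.123 in spleen. With single libraries left out it ran from -0.160 to 0.134 in kidney, -0.539 to 0.152 in liver, -0.192 to 0.273 in lung, -0.232 to 0.123 in muscle, 0.131 to 0.386 in skin and -0.417 to -0.105 in spleen.

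The log2 fold change of Sox2 in skin, 0.03, was -0.024 without a sex term, -0.15 with females only and -0.53 without the doubted library, and ran from -0.53 to 0.25 with single libraries left out; in lung it ran from -0.80 to -0.20. Myc in lung was -0.067 without the doubted library. With single libraries left out Klf4 ran from -0.0074 to 0.43 in kidney, 0.19 to 1.00 in liver, -0.10 to 0.45 in lung, -0.63 to 0.25 in muscle, -1.36 to -0.22 in skin and 0.64 to 0.81 in spleen, and Myc from -0.014 to 0.71 in kidney, 1.12 to 1.88 in liver, -0.067 to 0.51 in lung, -1.15 to -0.53 in muscle, -1.09 to -0.17 in skin and 0.28 to 0.49 in spleen. Msr1 in B6 liver was 0.14 without the doubted library, in place of -3.81, and ran from -4.64 to 0.14 with single libraries left out. The macrophage list in 4F lung, with a median of 0.69, turned to -0.03 without treated replicate 2, and with single libraries left out ran from -0.028 to 1.15. The matrix list in 4F skin, with a median of 0.28, turned to -0.18 without untreated replicate 2 and to -0.12 without either male, and was 2.18 without untreated replicate 1.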

Other observations

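The test of this part was chosen after the result was seen. Genes of senescence and secreted inflammatory factors differed in direction between tissues of 4F mice. In treated liver the list had a median log2 fold change of 0.54 (15 of 18 higher), in muscle -1.05 (4 of 17) and in spleen -0.39 (4 of 19). Camera called these with its preset correlation only, with adjusted p = 0.795, 0.441 and 0.664 with an estimated correlation. In spleen, Il1b, an inflammatory cytokine, stood at 36.8 ± 14.5 against 112 ± 89.7 CPM, and Il6, another, at 1.05 ± 0.50 against 1.95 ± 0.57 CPM (SD, n = 3 each), and the call ended without untreated replicate 1 (median -0.05, camera adjusted p 0.154). In muscle, Mmp12, a macrophage elastase, held 438 CPM in untreated replicate 3 and at most 1.74 CPM in the other 4F libraries; without either male, that library or treated replicate 1, which leaves the females compared, the median was -0.02 (0.533) and -0.04 (0.731), and without untreated replicate 1 -1.82. In liver the call ended without untreated replicate 2 (0.12, 0.711), without treated replicate 3 (0.28, 0.242) and without treated replicate 2 (0.51, 0.0578).

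Muscle of treated 4F mice also held more transcripts of MHC class II genes, with a median of 1.38, and the call has an adjusted p of 0.441 with an estimated correlation; the median was 0.89 without untreated replicate 2. Saa2, an acute-phase protein made by liver, held 0.0334, 2.19 and 11.6 CPM in treated and at most 0.0289 CPM in untreated 4F muscle, and Uroc1, a liver enzyme of histidine breakdown, 0.268, 6.16 and 2.12 against at most 0.202 CPM.

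Among the 4F females, untreated replicate 2 gave the most genes at an unadjusted p under 0.05 when set against the other 3. Of the 10 groupings, 4 place both males on 1 side and so, with sex in the model, compare 1 female with 3, with the spread taken from the other groups. Within these 4, the grouping of untreated replicate 2 gave 4479, 1089, 2639, 3330, 5126 and 2486 such genes in kidney, liver, lung, muscle, skin and spleen, against at most 1914, 392, 900, 322, 2044 and 1091 for any other female. Past the threshold it gave 776, 3, 22, 0, 1 and 5, so muscle gave no call, and in skin untreated replicate 1 gave 43. A hypothesis is 1 animal or batch behind that replicate number in every tissue. As a test, the difference between untreated females 2 and 1 over 11365 genes was compared between tissues: its Spearman correlation had a mean of 0.162 over the 15 pairs of tissues and was above 0 in 13 of them, and of the 32 ways to swap the 2 females within tissues no other gave as high a mean (highest other 0.126). This fits the hypothesis, but it covers both replicates, and an animal and a batch cannot be told apart. Fkbp5, a gene induced by glucocorticoids, was higher in that replicate than in the other untreated 4F libraries in every tissue, for example 436 CPM against 44.3 and 62.0 CPM in skin and 329 against 39.3 and 83.6 CPM in liver, and Cirbp, an RNA-binding protein induced by cold, held 156 CPM against 62.0 and 83.7 CPM in skin.

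Gt(ROSA)26Sor, the transcript of the Rosa26 locus, held 2.50 ± 0.24 CPM in treated and 5.61 ± 1.49 CPM in untreated 4F liver (SD, n = 3 each), and 9.23 ± 0.40 and 13.3 ± 3.91 CPM in treated and untreated B6 liver (n = 2 each). In lung Gt(ROSA)26Sor held 8.80 ± 0.11 against 14.1 ± 1.68 CPM in 4F mice. Untreated 4F lung replicate 2 held 1326 CPM of Myh8, a myosin of developing muscle, and 92.7 CPM of Krtdap, a protein of cornifying epithelium, against at most 0.0645 CPM of each in the other 4F lungs. Untreated B6 spleen replicate 2 held 2327 CPM of Mki67 and 34260 CPM of Hbb-bs, an adult globin, against 346 and 4896 CPM in its fellow.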
